A study of Mus musculus with 9 samples.

How the data were processed

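Expression was measured in LSK cells, the lineage-negative, Sca-1-positive and Kit-positive fraction of mouse bone marrow that holds stem cells and early progenitors. Per the labels, the mice were male C57BL/6 animals aged 12 weeks, and the cells were sorted by flow cytometry 6 days after 5-fluorouracil at 150 µg/g. Socs2 knockout mice gave 4 arrays and wild-type mice gave 5. Per the labels' protocols, 250 pg of total RNA was amplified with the NuGEN WT-Ovation Pico system, labelled with biotin and hybridised to Illumina mouse bead arrays. Groups and replicate numbers were taken from the sample titles. The labels do not say whether each array came from a separate mouse or from a pool, so p-values measure the spread between these arrays, which may be partly technical.

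The authors deposited processed values on a log scale, used here as log2 values; the R package lumi is named in the submitters' processing notes, with its version not given. The background correction, the exact transformation (plain log2 or variance stabilised) and the normalization method are not given in the sources used here. Array medians lay between 6.91 and 7.18, and a large part of the probes piled up near that level, so differences involving dim probes are compressed. If the transformation was variance stabilising, folds of dim genes are understated. A non-normalized table was not used: its 18 columns of per-array values carry chip positions that no label gives, and columns were never matched by order or by values. The analysis fixed before the data were examined would have started from that table, with background correction and a filter on detection p-values. It could not be run, and the authors' deposited log2 values took its place, with a minimum value in place of detection.

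Of 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. The Entrez identifiers of 34807 probes matched the current gene table, and 0 symbols changed. Probes with several symbols were left out, and unnamed probes were tested separately. A probe entered when its value was above 7.5 on at least 4 of the 9 arrays. That minimum was chosen from the distribution of all probes, before any test. A gene above 7.5 in 1 genotype alone could meet the filter with 4 of the 5 wild-type arrays, but only with all 4 knockout arrays. The probe with the highest mean over all arrays stood for its gene, which left 8543 genes.

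Genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes tested) in R 4.3.3, with no covariate. Adjusted p under 0.05 was the threshold. Single values and list scores were compared with an exact two-sided permutation test over the 126 splits of 9 arrays into 4 and 5, whose smallest p is 0.0159. A gene whose knockout arrays, or wild-type arrays, all lay at or below 7.5 has only a bound there, and its fold was computed against 7.5 and written "at least". The 25 gene lists were written before the data were examined. Lists with at least 5 measured members, 24 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. A list score is the mean over members of the deviation from each gene's mean, relative to all genes tested. Of 729 list entries, 678 had a named probe; the others are not analysed here.

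Named genes followed a rule set before the data were examined. It takes Socs2, then per direction the genes past the threshold or, with fewer than 10, the 10 genes with the smallest unadjusted p, described as ranked and not called. It adds up to 4 members with the smallest p in each list, and abundant members of the lists of other cell types. Predicted and clone-only symbols were passed over, which affected 2 symbols.

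The procedure was tested on simulated data for 8543 genes, each with its real mean and spread. Noise was drawn independently for each gene and array. It had no correlation between genes, no low-signal arrays and no floor, so the counts below need not hold for the real arrays. Of 50 genes changed by 1 on the log2 scale, 0 were recovered. Recovery was 15 of 50 at 2, 29 of 50 at 3 and 34 of 50 at 4, with 3 false calls. The number of arrays limits the precision of every value. Alternatives covered the filter on dim probes, the replicate number as a block, array weights, the variance model, the choice of probe, each array left out in turn and other set tests. A further 6, chosen after seeing the data, covered the 2 low-signal arrays, scaling, other minimum values and a floor.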

Results

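The data are 9 bead arrays of bone-marrow LSK cells taken 6 days after 5-fluorouracil, a drug that kills cycling cells and draws stem cells into division. They comprise 5 wild-type and 4 Socs2 knockout arrays, and the series asks which transcripts depend on Socs2 in this setting. Wild-type arrays had 34.3% to 35.4% of probes above 7.5, and knockout arrays 3 and 4 had 35.1% and 34.8%. Knockout arrays 1 and 2 had 31.1% and 31.0%, and their median correlations with the other arrays were 0.52 and 0.49, against 0.65 to 0.72 for the rest. No pair of arrays was near identical, the highest correlation being 0.79.

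**Figure D1:**
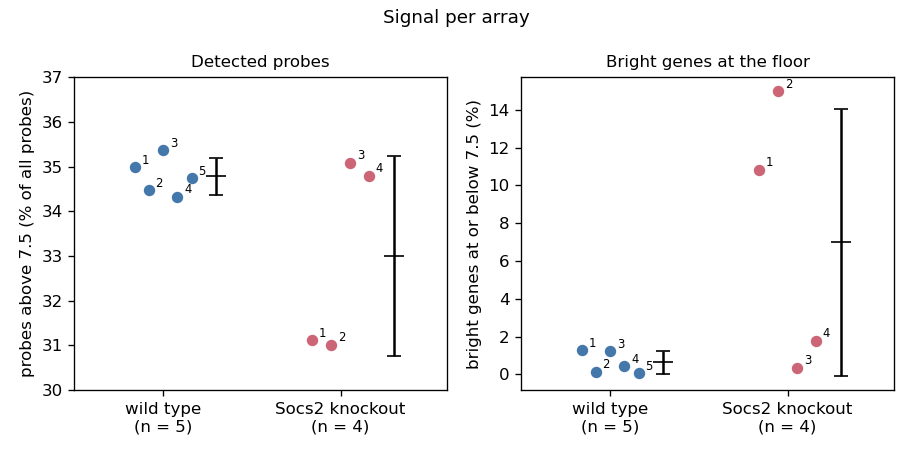
Percent of all probes above 7.5 (left) and percent of 2804 bright genes at or below 7.5 (right) for each array, by genotype; points are arrays with their replicate numbers, and bars show mean and SD (wild type n = 5, knockout n = 4). Knockout arrays 1 and 2 sit apart in both panels, at 31.1% and 31.0% on the left and 10.8% and 14.98% on the right.

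Socs2, a cytokine-inducible suppressor of JAK-STAT signalling encoded on chromosome 10, was the targeted gene and fell in the knockout arrays. Its brighter probe (ILMN_2628178) read 9.67 ± 0.40 in wild-type arrays (SD, n = 5) and 6.71 ± 0.10 in knockout arrays (SD, n = 4). All 4 knockout values lay at or below 7.5, so the transcript was at least 4.51-fold lower. The log2 difference was -2.96 (SE 0.34, limma adjusted p = 0.036), and the exact permutation p of 0.0159 is the smallest this design allows. The 2 genotypes did not overlap, with wild-type values from 9.38 to 10.36 and knockout values from 6.58 to 6.80. A second Socs2 probe (ILMN_1250749) was above 7.5 on 1 array only, wild-type array 2 at 8.93, and its difference of -0.45 had an exact p of 0.349. The call did not hold when most single arrays were left out: it passed without wild-type array 3 (adjusted p = 0.025), and without each of the others the adjusted p lay above 0.05, up to 0.168. Which part of the gene was deleted is not given in the sources used here, so the place of each probe relative to it was not checked.

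**Figure D2:**
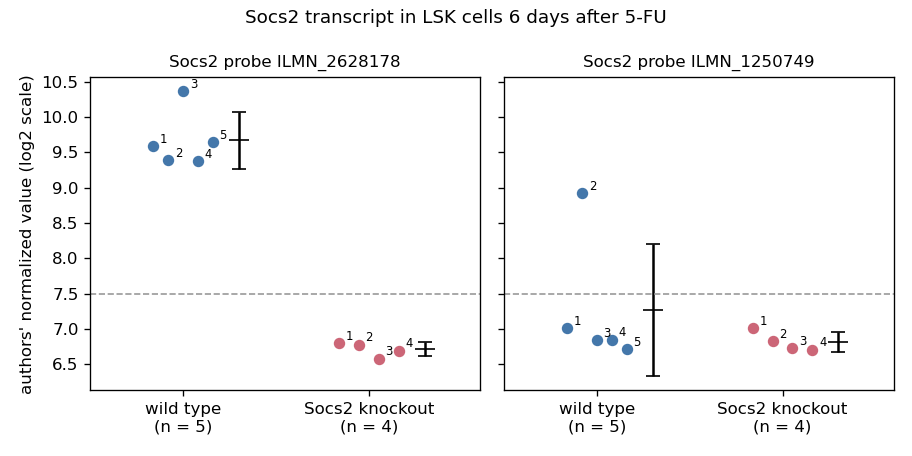
Normalized value (log2 scale) of both Socs2 probes on each array, by genotype; points are arrays with replicate numbers, bars show mean and SD, and the dashed line marks 7.5. For ILMN_2628178 the 5 wild-type arrays lie between 9.38 and 10.36 and the 4 knockout arrays between 6.58 and 6.80; for ILMN_1250749 wild-type array 2 alone lies above the line.

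Of 8543 genes tested with limma, 1 passed the adjusted threshold, and it was Socs2. At an unadjusted p under 0.05 there were 868 genes, 196 higher and 672 lower in the knockout, where 427.2 would be expected by chance. The lower share was 77.4%, which became 67.0% with each array centred on its median and 53.7% without knockout arrays 1 and 2 (253 higher, 294 lower). With no filter on dim probes it was 61.7% (571 higher, 920 lower), and with values above 7.5 on all 9 arrays 61.9% (129 higher, 210 lower). Without wild-type array 3 the adjusted threshold was passed by 7 genes: Sync, Dab2, P2ry1, Socs2, Kansl3, Cep170 and Sidt2, of which Sync, Dab2, P2ry1 and Kansl3 are named only because their values were seen. Across all genes the median log2 difference was -0.18, or -0.06 with each array centred on its median, -0.0076 with no filter and -0.03 with all 9 arrays above 7.5, and the median residual SD was 0.92. The 2 genotypes were fully apart in 316 genes, or 3.70%, against 1.59% by chance.

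The genes ranked next to Socs2 were not called, and their values follow as ranked differences with limma adjusted p from 0.169 to 0.233. On the lower side, Baz2b, a bromodomain protein, had a log2 difference of -2.92 (SE 0.47). Vps37a, a subunit of the ESCRT-I sorting complex, had -2.90 (SE 0.48), and Cep170, a centrosomal protein, had -2.97 (SE 0.50). The deubiquitinase Yod1 had -2.59, the endosomal protein Rabep1 -2.21 and the galactosyltransferase B3galt6 -2.43. Ints6, of the Integrator complex, had -2.66, and the nucleic-acid-binding protein Kin had -2.63. Both Rabep1 and Kin were at or below 7.5 on all 4 knockout arrays, so they were at least 3.48-fold and at least 4.68-fold lower. Knockout means of Baz2b (7.08), Vps37a (7.13), Cep170 (7.23) and Ints6 (7.48) also lay below 7.5, so the size of these differences is uncertain. Ugcg, the glucosylceramide synthase, had -2.02 (SE 0.37), from 11.15 ± 0.29 in wild type (SD, n = 5) to 9.13 ± 0.51 in the knockout (SD, n = 4).

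On the higher side, Sidt2, a lysosomal membrane protein, had a log2 difference of 2.37 (SE 0.46). The solute carrier Slc45a4 had 1.64 (SE 0.32), and the small GTPase Arf2 had 1.66 (SE 0.33). Cops8, of the COP9 signalosome, had 2.16, and Sdhaf4, an assembly factor of succinate dehydrogenase, had 2.11. Wild-type means of Slc45a4 (7.37) and Cops8 (7.07) lay below 7.5, so the size of their differences is uncertain. Galnt12, which starts mucin-type O-glycosylation, was at or below 7.5 on all 5 wild-type arrays and at least 3.99-fold higher in the knockout, a bound of 2.86 without knockout array 1. Cacng3 had 1.97, Nudt5 had 1.81, the calcium-dependent protease Capn2 had 2.08 and the DNA repair protein Mgmt had 2.36. Genotypes were fully apart in 18 of these 19 genes, the exception being Capn2, but ranking by p in these same arrays selects for such separation. Of the 10 with several probes above the filter, 5 had probes of opposite sign: Baz2b, Rabep1, Ints6, Sidt2 and Slc45a4.

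**Figure D3:**
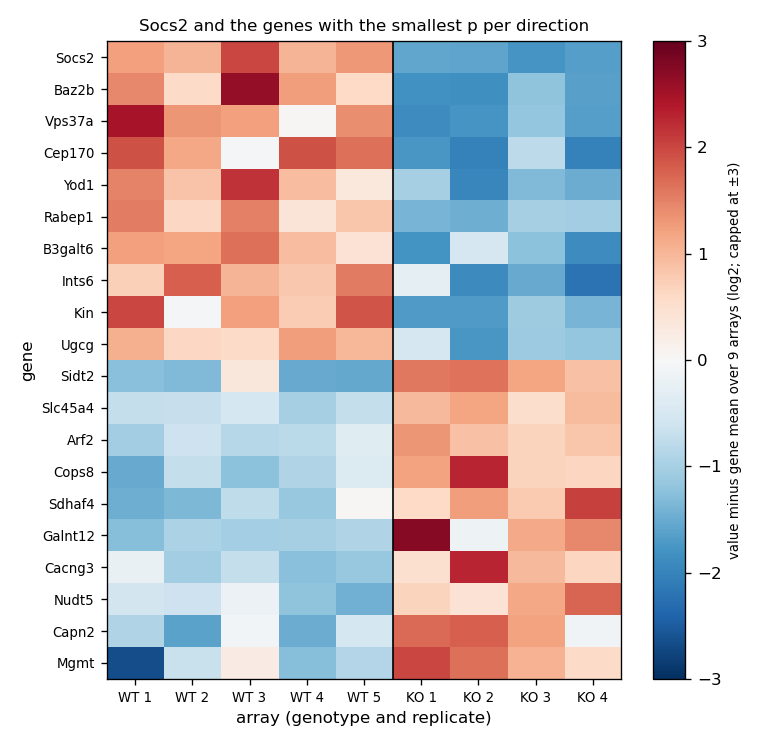
Value of each gene on each array minus its mean over 9 arrays (log2, colour capped at 3 in each direction) for Socs2 and the 19 ranked genes, with wild-type arrays on the left of the line and knockout arrays on the right. Socs2 passed the adjusted threshold, with a log2 difference of -2.96, and the other 19 did not, with adjusted p from 0.169 to 0.233.

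The gene lists below were read with and without knockout arrays 1 and 2. Of 97 genes that the naming rule took from the lists, 46 had a difference over 1.5 times smaller, or of the other sign, without these arrays. They made up 36 of the 67 with negative and 10 of the 30 with positive differences. Those named below include Gbp3, Cdk6, Tek, Csf2ra, Csf2rb, Rb1, Rbl1, Gfi1, Birc3, Ccl4, Rps20, Vcam1, Selp, Ly6d, Cd8b1, Emcn, Hdc and Mcpt8. With a single array left out, 52 of the 97 had a difference over 1.5 times smaller or of the other sign, and 27 could be over 1.5 times larger. For such genes named below, the smallest value stands in brackets with the array left out. Probes of opposite sign were found for Mcm10, Spred2, Poc1b, Csf2rb, Egfl7, Vcam1, Trp53inp1, Rplp0, Tsc1, Cxcl12, Cd27, Cpa3 and Ccng1. List medians are followed by their range with single arrays left out. As for the ranked genes, the size of a difference is uncertain where a group mean lay below 7.5.

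Interferon-response genes were lower in the knockout in 26 of 32 measured members, with 9 lower and 0 higher at an unadjusted p under 0.05 and 0 past the threshold over all genes. The list median was -0.70, from -0.88 without wild-type array 3 to -0.48 without wild-type array 4, or -0.53 relative to all genes. The relative median was -0.34 without wild-type array 2, -0.32 without wild-type array 4 and -0.019 over members above 7.5 on all 9 arrays, a filter that leaves out genes at background on any array. Oasl2, an antiviral protein of the oligoadenylate synthetase family, had a log2 difference of -3.05 (SE 0.57) and was the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.0081). Trim30a had -2.56 and Gbp3 -1.29. Ifih1, a sensor of viral RNA, was at or below 7.5 on all 4 knockout arrays, hence at least 2.07-fold lower. The list did not pass camera (p = 0.0022, adjusted p = 0.053), and it had p = 0.168 with an estimated correlation. Scores were 0.23 ± 0.48 in wild type (SD, n = 5) and -0.28 ± 0.17 in the knockout (SD, n = 4), with an exact p of 0.127. Wild-type arrays 3 and 5, at -0.24 and -0.33, lay within the knockout range of -0.43 to -0.10. Without knockout arrays 1 and 2 the median was -0.45 and the camera adjusted p 0.067. Leaving out single arrays brought the list past the threshold in 3 cases, without wild-type array 3 (adjusted p = 0.0077), wild-type array 5 (0.0036) or knockout array 1 (0.043). With an estimated correlation in the same 3 cases the adjusted p was 0.949, 0.714 and 0.958.

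Cytokine signalling, the pathway in which Socs2 acts, was read from 3 lists, none of which passed. STAT5 and cytokine-inducible targets were below 0 in 13 of 17 members, with a median of -0.46 and a camera p of 0.084 (adjusted p = 0.404). The median ranged from -0.74 without knockout array 1 to -0.42 without knockout array 2. Among them the cell-cycle kinase Cdk6 had -1.71 (SE 0.70), or -1.07 without knockout arrays 1 and 2. Its partner cyclin D1 (Ccnd1) had -1.04 (SE 0.45, and -0.69 without knockout array 4). Spred2 had -1.61 (-0.88 without knockout array 2) and Socs3 -1.41 (-0.92 without wild-type array 3). Their score was 0.18 ± 0.24 in wild type (SD, n = 5) and -0.22 ± 0.25 in the knockout (SD, n = 4), with an exact p of 0.0476 (0.496 after adjustment over the lists). Knockout arrays 1 and 2 scored -0.21 and -0.57. Knockout arrays 3 and 4 scored -0.02 and -0.08, within the wild-type range of -0.12 to 0.50. Without knockout arrays 1 and 2 the list median was -0.43, with a camera adjusted p of 0.794. JAK-STAT components and the SOCS family had 2 of 21 members lower at an unadjusted p under 0.05, Jak2 at -1.47 and Stat2 at -1.31, with a median of -0.29 and a camera adjusted p of 0.872. That median ranged from -0.39 without knockout array 4 to 0.05 without knockout array 2, and was -0.03 without knockout arrays 1 and 2. Receptors had a median of -0.28 over 21 members (camera adjusted p = 0.918), -0.56 without knockout array 4 and -0.22 without knockout array 2, with Csf1r, the receptor of macrophage colony-stimulating factor, at 1.46 (SE 0.42) and Tek at -1.31. Csf2rb and Csf2ra had -1.21 and -0.99. Without knockout arrays 1 and 2 they had -0.20 and -0.43, and Tek had -0.86. The knockout mean of Tek over all 4 arrays (7.26) lay below 7.5, so the size of its difference is uncertain.

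The cell cycle lists did not pass either. DNA replication and G1/S genes had a median of -0.04 and a mean of 0.02 over 37 members, with 1 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.476). The median ranged from -0.10 without knockout array 3 to 0.12 without knockout array 1, and was 0.28 without knockout arrays 1 and 2 with a camera p of 0.029 (adjusted p = 0.348). The origin-firing factor Mcm10 had 1.26, with 4 probes from -1.13 to 1.26 and 0.28 for their mean, and the flap endonuclease Fen1 1.22, while Clspn had -1.24 and E2f1 -1.51. The score of this list was higher on all 4 knockout arrays than on all 5 wild-type arrays, at 0.138 ± 0.127 (SD, n = 4) against -0.110 ± 0.045 (SD, n = 5). Its exact p was 0.0159, or 0.397 after adjustment over the 25 lists. Mitosis and G2/M genes were below 0 in 24 of 34 members, with a median of -0.36 (camera adjusted p = 0.872), Hmmr at 1.34 and cyclin A2 (Ccna2) at -1.92 (-1.26 without knockout array 2). The median ranged from -0.50 without knockout array 3 to -0.13 without knockout array 1, and was 0.06 without knockout arrays 1 and 2, where Ccna2 had -0.17. Inhibitors of cyclin-dependent kinases and regulators of G0 had a median of -0.02 over 12 members (camera adjusted p = 0.999), with Rbl1 at -1.26 (-0.59 without knockout array 1) and Rb1 at -1.64. Their median was -0.35 without knockout array 4, 0.19 without wild-type array 5 and 0.26 without knockout arrays 1 and 2, where Rbl1 had -0.45 and Rb1 -0.62.

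**Figure D4:**
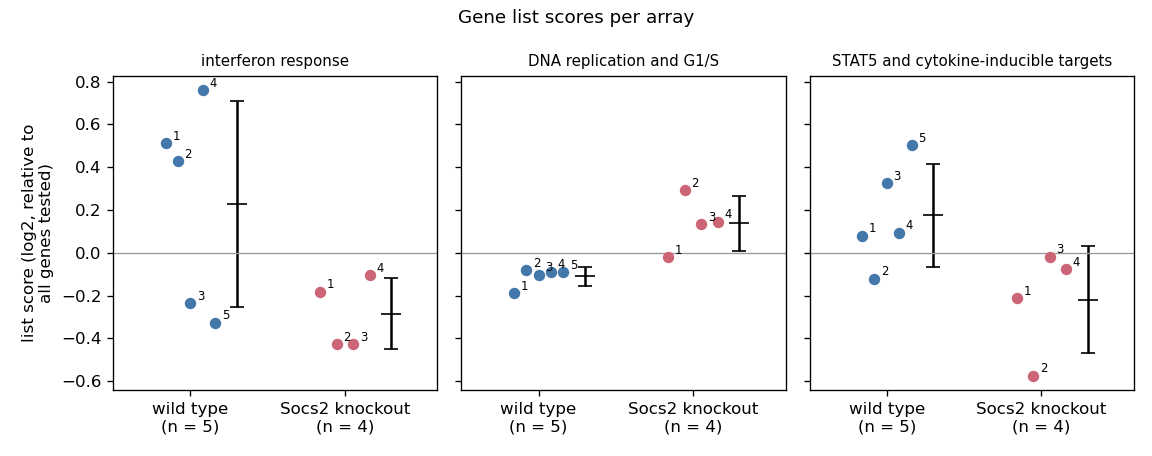
Score of each array (log2, relative to all genes tested) for the interferon, DNA replication and STAT5 target lists, by genotype; points are arrays with replicate numbers and bars show mean and SD (wild type n = 5, knockout n = 4). Interferon scores overlap between genotypes through wild-type arrays 3 and 5, whereas DNA replication scores do not overlap (exact p = 0.0159 before adjustment, 0.397 after).

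Genes of stem cell identity and quiescence had 2 members higher and 4 lower of 34 at an unadjusted p under 0.05, with a median of -0.12 (camera adjusted p = 0.918). The Polycomb gene Bmi1 had -1.55 (SE 0.52), Hoxb4 -1.86 (SE 0.68) and Gfi1 1.43. The knockout mean of Hoxb4 (7.27) lay below 7.5, so the size of its difference is uncertain. Bmi1 had -0.63 without knockout arrays 1 and 2, and the list median ranged from -0.50 without wild-type array 1 to -0.08 without wild-type array 5. Fgd5, a stem cell marker, was at or below 7.5 on all 5 wild-type arrays and at least 2.32-fold higher in the knockout, a bound of 1.51 without knockout array 2. In the p53 list, 12 of 16 members were below 0, with a median of -0.59 (camera adjusted p = 0.607). It ranged from -0.78 without knockout array 4 to -0.27 without knockout array 1, and was -0.11 without knockout arrays 1 and 2. The median was -0.13 with no filter on dim probes and -0.36 with the mean of all probes. The pro-apoptotic gene Bbc3 was at or below 7.5 on all 4 knockout arrays and above it on 4 of 5 wild-type arrays. It was hence at least 3.77-fold lower, a bound of 3.08 without wild-type array 2 and 5.83 without wild-type array 4. Trp53inp1 had -1.54 (-0.70 without knockout array 1) and Sesn1 0.97.

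The stress and inflammatory lists did not pass. Immediate early genes had 3 of 16 members lower at an unadjusted p under 0.05, with a median of -0.62 (camera adjusted p = 0.454; with no filter 0.035, and adjusted p = 0.737 there with an estimated correlation) that ranged from -0.73 without knockout array 3 to -0.47 without wild-type array 5 and was -0.16 without knockout arrays 1 and 2. Klf6 had -2.58, Zfp36 -1.96, Jun -1.57 and Egr1 -1.91 (-0.91 without knockout array 2). Without these arrays Klf6 had -0.68, Zfp36 -0.31, Egr1 0.05 and Jun -1.78. NF-kB and inflammatory genes had a median of -0.10 over 11 members (camera adjusted p = 0.918), with the apoptosis inhibitor Birc3 at -2.05 and the chemokine Ccl4 at -1.51 (-0.996 without wild-type array 4). Their median was -0.46 without knockout array 2, 0.10 without knockout array 4 and -0.37 without knockout arrays 1 and 2.

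Ribosomal protein genes were above 0 in 21 of 28 members, with a median of 0.14 and a camera p of 0.028 that did not pass after adjustment (0.339). The list passed with no filter (adjusted p = 0.035) and with the variance trend (0.0035), but with an estimated correlation the adjusted p was 0.737 and 0.843. Its median ranged from 0.11 without wild-type array 3 to 0.24 without knockout array 4, and was 0.07 without knockout arrays 1 and 2. Rpl4 had 1.499 (0.84 without wild-type array 3), while Rps20 had -1.78 and Rplp0 -1.03. Oxidative phosphorylation genes were above 0 in 24 of 39 members, with a median of 0.14 (camera adjusted p = 0.404), Sdhb at 0.97 and Ndufc1 at -1.21. Their median was -0.00043 without knockout array 1 and 0.18 without wild-type array 2. Ribosome biogenesis genes and MYC targets had a median of -0.12 over 28 members (camera adjusted p = 0.999), with Rrp9 at 1.77 and Ppan at -2.09, and the median ranged from -0.31 without knockout array 3 to 0.045 without knockout array 1. Glycolysis and hypoxia genes had a median of 0.13 and a mean of -0.04 over 24 members (camera adjusted p = 0.563), with P4ha1 at 0.50 (0.18 without knockout array 4) and Bnip3l at -1.10 (-0.55 without knockout array 1), and a median from -0.04 without wild-type array 1 to 0.21 without wild-type array 4.

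Markers of other marrow cells were examined because the sort gate could admit some of them. Monocyte, macrophage and dendritic markers had a median of -0.40 over 22 members (camera adjusted p = 0.751), with Csf1r at 1.46, Vcam1 at -1.57 and Mrc1 at -1.92. The median ranged from -0.64 without knockout array 3 to -0.18 without wild-type array 1, and was -0.13 without knockout arrays 1 and 2, where Mrc1 had -0.47, and another Vcam1 probe had 1.57. Its most abundant members, Siglech and Lyz1, differed by 0.03 and -0.21. Erythroid markers had a median of 0.08 over 10 members (camera adjusted p = 0.404), from 0.041 without wild-type array 1 to 0.28 without knockout array 2. The alpha-globin gene Hba-a1 had a log2 difference of 3.37 (SE 0.82), past the threshold when adjusted over the list alone (adjusted p = 0.019) and not over all genes. Its difference was 2.30 without knockout arrays 1 and 2. Among wild-type arrays only array 5 (9.10) read above 7.5, the next value being 7.30, so the size of the difference is uncertain. Beta-globin genes Hbb-b2 and Hbb-bt had 0.70 and 0.51 (0.24 and 0.035 without knockout array 1), and became -0.20 and -0.36 without knockout arrays 1 and 2. Granulocyte progenitor markers had a median of -0.20 over 9 members (camera adjusted p = 0.918), with Mpo (-0.98 without knockout array 3) and Ctsg each at -1.58 and a median from -0.41 without wild-type array 1 to 0.083 without wild-type array 4 and 0.027 without knockout arrays 1 and 2. Mature neutrophil markers were above 0 in 5 of 7 members, with a median of 0.26 (camera adjusted p = 0.607), Padi4 at 0.61 (0.0024 without knockout array 2), Hp at 0.60 (-0.16 without knockout array 4), Anxa1 at -0.82 (-0.36 without knockout array 1) and S100a9 at -0.64. Their median was 0.0024 without knockout array 2, 0.61 without wild-type array 5 and -0.23 without knockout arrays 1 and 2. It was 0.0062 with no filter on dim probes and -0.64 with a minimum value of 8. Megakaryocyte and platelet markers had a median of -0.20 over 10 members (camera adjusted p = 0.872), with Selp at -1.19 (-0.70 without knockout array 1) and the abundant Gp9 at -0.32, and a median from -0.28 without knockout array 4 to 0.03 without wild-type array 4 and -0.085 without knockout arrays 1 and 2. Lymphoid progenitor and B-cell markers had a median of 0.03 over 14 members (camera adjusted p = 0.480), with Ly6d at 1.37 (0.88 without knockout array 2) and Jchain at -0.01, and a median from -0.17 without knockout array 3 to 0.45 without knockout array 1. T- and NK-cell markers had a median of -0.33 over 10 members (camera adjusted p = 0.872), with Cd8b1 at -0.87 and Prf1 at -0.10, and a median from -0.52 without wild-type array 4 to -0.063 without knockout array 2 and -0.098 without knockout arrays 1 and 2. Endothelial and stromal markers had a median of -0.19 over 11 members (camera adjusted p = 0.898), with Egfl7 at 0.75 (0.40 without wild-type array 4) and Emcn at -1.28 (-0.65 without wild-type array 2). Their median was -0.49 without wild-type array 2, 0.41 without knockout array 1 and 0.49 without knockout arrays 1 and 2. Mast cell and basophil markers had only 4 measured members and were not tested as a list; Mcpt8 had -2.08 and Hdc 1.42 (0.60 without knockout array 2).

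Neighbours of Socs2 on chromosome 10 had a median of 0.02 and a mean of -0.16 over 16 members, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.918). Poc1b had -1.69 (-1.11 without knockout array 1) and Nedd1 -1.04 (-0.64 without knockout array 2), and the median ranged from -0.21 without wild-type array 3 to 0.11 without wild-type array 5. Median, mean and camera direction differed in sign for the neighbours, for DNA replication, for glycolysis, for the kinase inhibitors, and for the granulocyte progenitor, megakaryocyte and endothelial lists. Camera sets a list against all other genes, whose median lay below 0. No list passed camera with an estimated correlation, where the smallest adjusted p was 0.932, or fry, where it was 0.350.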

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

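Values far from the rest of their own group were picked out by the gap to the nearest other array, and 25 of 294 groups met that condition where chance gives 14.7. Among wild-type arrays, array 3 stood apart for Socs2 (10.36), Sidt2 (9.605), Klf6 (9.75) and Rpl4 (6.87). Wild-type array 1 stood apart for Poc1b (8.996), Bnip3l (6.99) and Hdc (9.63). Array 2 did so for Fabp4 (7.92) and the second Socs2 probe (8.93), and array 4 for Mxi1 (7.55), Ctsg (7.38) and Bbc3 (6.91). In array 5 the alpha-globin gene Hba-a1 read 9.10, against 7.30 for the next wild-type array. List scores stood apart for mature neutrophil markers in wild-type array 5 (0.85) and for DNA replication in wild-type array 1 (-0.19).

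Among knockout arrays, array 4 stood apart for Hoxb4 (8.68), Ccl4 (9.69) and Hif1a (9.71). Knockout array 3 stood apart for Jak2 (7.96), Mcpt8 (11.11) and, at the low end, Mpo (6.83). Array 2 did so for Fen1 (11.67) and for the score of the Socs2 neighbours (0.46), and array 1 for Trim30a (10.11) and for the endothelial and stromal score (-1.21).

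Probes with no gene name in the annotation lie outside the comparison of genes, and 2 of 3193 passed a limma test of their own, added after the data were seen, at an adjusted p under 0.05. Probe ILMN_2529432 had a log2 difference of -3.16 (adjusted p = 0.0010), from 10.28 ± 0.33 in wild type to 7.12 ± 0.15 in the knockout, at least 6.84-fold lower. Probe ILMN_1243996 had -2.38 (adjusted p = 0.021), from 9.66 ± 0.36 to 7.28 ± 0.37. In one test of all 16526 named and unnamed probes, 2 passed: ILMN_2529432 and the Socs2 probe ILMN_2628178.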

How the results depend on the processing

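Socs2 stayed lower in all 20 alternatives that tested it (-3.04 to -2.17), and it passed the adjusted threshold in 7 of them, with adjusted p from 0.0073 to 0.633. Arrays without a detection value limit what dim genes can show: 7.5 served as the level of background. Not run were no background correction, normexp with an offset of 50 and median scaling, which need the table not used here, and the chip as a block, since chips were not matched to samples. The authors' values, planned as an alternative, became the main setting. Of the alternatives reported here, 7 were chosen after seeing the data: leaving out both low-signal knockout arrays (1 and 2), centring, a quantile step, a higher and a lower minimum value, a floor at 7.5, and an estimated correlation in each setting in which a list passed. Of 117 named genes, 94 kept their direction in all alternatives, as did 11 of 24 lists; the cause was not tested for the changes below, apart from fewer arrays or fewer genes where these were left out.

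Genes past the threshold numbered 1 in the main setting and 2 with no filter on dim probes, 3 with values above 7.5 on all 9 arrays (where Socs2 has no value), and 0 with the variance trend, without both low-signal arrays, with centring or with the floor. Leaving out single arrays gave 0 to 7 genes. At an unadjusted p under 0.05 the count was 1491 with no filter (571 higher, 920 lower), 339 with all 9 arrays above 7.5 (129 higher, 210 lower) and 547 without both low-signal arrays. The Socs2 difference lost its call at -2.96 with the variance trend, -3.04 without both low-signal arrays, -2.84 with centring and -2.17 with the floor, and ranged from -3.03 to -2.79 with single arrays left out. Lists past the threshold numbered 0 in the main setting, 3 with no filter (interferon response, ribosomal proteins and immediate early genes), 1 with array weights, 2 with the variance trend (interferon response and ribosomal proteins), 1 with the mean of all probes, 1 with the lower minimum, and 0 to 1 with single arrays left out. Interferon response was past it in 9 of 23 alternatives, with adjusted p from 0.00023 to 0.988. All these list calls, in 9 settings, use a preset correlation of 0.01; with an estimated correlation in the same settings 0 lists passed, with adjusted p from 0.714 to 0.997. In the main setting interferon response had an adjusted p of 0.932 with an estimated correlation and 0.350 with fry.

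Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.02, -0.05, -0.07 and 0.04, and 2 of 4 knockout arrays correlated best with their own number. With the replicate number as a block, a fit to which wild-type array 5 adds nothing because no knockout array shares its number, 0 genes and 1 list passed, 629 genes had an unadjusted p under 0.05, Socs2 stood at -2.97 (adjusted p = 0.633) and interferon response had an adjusted p of 0.0028 (adjusted p = 0.961 with an estimated correlation). Under the block the stem cell list (adjusted p = 0.885) and the T- and NK-cell list (0.958) changed direction. Without wild-type array 5 and with no block, Socs2 was likewise at -2.97, interferon response passed (adjusted p = 0.0036, or 0.714 with an estimated correlation) and both lists turned (0.908 and 0.987), so these changes are not put down to the block.

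Differences of single genes changed sign as follows. With all 9 arrays above 7.5, another probe stood for Poc1b (0.84), Tsc1 (0.58) and Trp53inp1 (0.028). With the mean of all probes, Cd27 was 0.32, Cpa3 0.34 and Rplp0 0.37. Without both low-signal arrays the differences were 0.28 for Nfkbiz, 0.16 for Nedd1, 0.072 for Mrpl42, 0.22 for Tsc1, 0.68 for Cxcl12, 0.50 for Fabp4, -0.20 for Hbb-b2, -0.36 for Hbb-bt, 0.55 for Bnip3l, 0.046 for Egr1, -0.011 for Ebf1, -0.077 for Itga2b, 0.17 for Spag5, 0.28 for Ccng1 and 0.37 for Rpl14. With single arrays left out, ranges crossed 0 for Fabp4 (-1.63 to 0.053), Cpa3 (-1.26 to 0.13), Mrpl42 (-1.26 to 0.32), Gata2 (-1.17 to 0.11), Pglyrp1 (-0.071 to 1.12) and Hp (-0.16 to 0.9995).

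Lists whose camera direction changed did so at these adjusted p-values. With no filter they were granulocyte progenitors (0.896) and megakaryocytes (0.493), and with all 9 arrays above 7.5 Socs2 neighbours (0.988) and megakaryocytes (0.804). Array weights turned the neighbours (0.990) and ribosome biogenesis (0.990), and the mean of all probes turned the neighbours, endothelial and ribosome biogenesis lists (0.996 each). Without both low-signal arrays the stem cell list had 0.643, ribosome biogenesis 0.665 and receptors 0.981, while neighbours, T and NK cells, neutrophils, megakaryocytes, mitosis and monocytes had 0.878 each. Centring turned the kinase inhibitors (0.958) and ribosome biogenesis (0.965), the quantile step turned the kinase inhibitors (0.994), the higher minimum (8) turned both (0.877 each) and the lower one the kinase inhibitors (0.903). With single arrays left out, adjusted p ranged from 0.818 to 0.986 for neighbours, 0.672 to 0.995 for kinase inhibitors, 0.786 to 0.995 for ribosome biogenesis, 0.348 to 0.995 for endothelial markers and 0.664 to 0.995 for receptors. The ranges were 0.664 to 0.964 for granulocyte progenitors, 0.672 to 0.958 for the stem cell list, 0.664 to 0.987 for NF-kB genes, 0.664 to 0.995 for T and NK cells, 0.669 to 0.958 for mitosis, 0.373 to 0.982 for monocytes and 0.249 to 0.986 for neutrophils.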

Other observations

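Genes that were bright on most arrays read at or below 7.5 on single arrays, which the comparisons of genotypes do not show. Of 2804 such genes, above 9.5 on at least 6 arrays, 10.8% were at or below 7.5 on knockout array 1 and 14.98% on knockout array 2, against 0.07% to 1.8% on the others. Among 3191 genes with 2 probes above the filter, the differences of both probes correlated across genes at 0.31, and 64.5% had the same sign; genes are not independent replicates.

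Tests chosen only after their results were seen are those that leave out both low-signal knockout arrays, the test of the filter, the 2 interferon tests on monocyte markers and on differences between mice, the splits for unadjusted and list counts, and the ratio restricted to certain pairs of arrays.

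More genes were lower than higher in the knockout. The lower share was 69.0% in the dimmest part of the genes and 85.7% in the brightest, the reverse of what loss of dim transcripts predicted. Differences of dim genes are compressed near 7.5, so a fall there is hard to detect, and such loss is not excluded. The 2 low-signal arrays may account for much of the excess of lower genes, as the share was 53.7% without them. An offset per array stays open, with 67.0% after centring, as does the filter, which wild-type arrays meet more easily, with 61.7% when it was dropped and 61.9% with all 9 arrays above 7.5. Chance could not be excluded, since 13 of 100 splits of the arrays, the real one included, gave as large a share on one side. All of these splits placed knockout arrays 1 and 2 on the same side, and the highest share with them apart was 72.7%. The count therefore does not separate chance from the 2 low-signal arrays. The share was 77.4% in the real split and 83.1% in the highest other.

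Interferon genes tended to be lower in the knockout. Without the low-signal arrays the list median was -0.45 in place of -0.70, and the camera p was 0.0028 (adjusted p = 0.067). That p rests on the preset correlation of 0.01, and with an estimated correlation the camera p over all arrays was 0.168. Knockout arrays 3 and 4 scored -0.43 and -0.10, overlapping wild-type arrays 3 and 5 (-0.24 and -0.33). Knockout arrays 1 and 2 scored -0.18 and -0.43, and the mean score was -0.27 over knockout arrays 3 and 4 against -0.28 over all knockout arrays. The scores therefore do not place the lowering in the low-signal arrays alone. The test cannot exclude them as a part of its source, because few knockout arrays remain and its p rests on the preset correlation. Fewer monocytes or dendritic cells stay open: 0 of the 5 brightest markers (Siglech, Lyz1, Cd74, H2-Ab1 and Lyz2) were higher by over 1 standard error, and the marker list had a camera p of 0.375. Against it, Csf1r, the member with the smallest p, was 1.46 higher (SE 0.42), but a single gene excludes nothing. Siglech differed by 0.03, while Lyz1 (-0.21), Cd74 (-0.44), H2-Ab1 (-0.55) and Lyz2 (-0.10) were below 0. The lineage-negative gate should remove such cells. Yet Siglech read 12.4 in wild type and 12.5 in the knockout, and Lyz2 11.8 and 11.7. Marker signal was thus present in both genotypes, and the gate does not decide the question. Differences between mice unrelated to genotype stay open. Scores of 2 wild-type arrays lay within or below the knockout range. Such overlap can also occur when genotype lowers the mean, so the test cannot tell these explanations apart. Chance could not be excluded, since 15 of 100 splits, the real one included, gave as small a camera p. That camera p was 0.0022 in the real split and 2.16e-06 in the smallest other. A lowering by genotype therefore stays a hypothesis.

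Loss of bright genes on single arrays may follow genotype or the amplification of little RNA, and the tests do not settle it. Knockout pairs of arrays shared such genes 1.41 times as strongly, relative to expectation, as mixed pairs, which met the bound of 1.2 set before the result was seen. Many of those pairs expect few shared genes, and over pairs with at least 3 expected, a restriction added after seeing the first ratio, it was 0.954. Knockout arrays 1 and 2 shared 102 genes where 45.5 were expected, and being both low in signal and both knockout they leave these explanations mixed. Random loss in amplification cannot be told apart from other sources: the loss fell from 6.44% among the dimmest genes to 0.456% among the brightest. A second bright probe of the gene was lost too in 54 of 88 cases (61.4%), between the bounds set for either reading. The overall rate of loss for second probes was 3.34%, so 2 probes of a gene tended to be lost together.

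Other splits of the arrays bear on the counts as well, and the real split is itself included in each count of 100. In 13 of 100 splits at least 1 gene passed the adjusted threshold, as in the real split, and the highest other count was 9, so chance could not be excluded for the number of called genes. At an unadjusted p under 0.05, 3 of 100 splits gave as many genes as the real 868, but this test was chosen after its result was seen. The highest other split gave 1013, another gave 872, and both placed the low-signal arrays together. Splits with these arrays together had a median of 482.5 genes and splits with them apart 341, which points to a structure of the samples, so a chance placement of these 2 arrays is not excluded as the source of the count. The smallest camera p over the lists (0.0022) was matched by 39 of 100 splits, with 3.42e-09 the smallest other.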
